A study of Arabidopsis thaliana with 6 samples.

How the data were processed

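Total RNA of Arabidopsis roots from 3 samples without cadmium and 3 with 200 µM cadmium for 6 h was labelled with biotin and hybridised to Affymetrix ATH1 arrays, per the labels' protocols. The deposited values are a linear intensity for each of 22810 probe sets and 6 arrays, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 combines the probes of a set into 1 signal and scales each array. The 2% trimmed mean of the deposited signals was 500 on the arrays of replicates 1 and 3, and 216 and 227 on those of replicate 2, so the scaling of the latter was different and its target is not given in the sources used here. All value columns were used.

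Groups and replicate numbers came from the sample titles. The sample descriptions number the replicates differently (titles 1, 2 and 3 are described as 3, 1 and 2) but pair the same arrays across groups. No label says what a shared number stands for. P-values measure the spread between the arrays, which the labels call biological replicates.

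Values were analysed as deposited on the log2 scale. A signal of 0 occurred 7 times, all on control replicate 2, and was set to that array's lowest positive signal. The 64 control probe sets were left out, as were probe sets whose mean signal over 6 arrays was under the 30th percentile (73.0), which left 15909. The fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with a two-sided moderated test and Benjamini-Hochberg adjustment, and a threshold of 0.05. The comparison of 3 against 3 arrays had 4 residual degrees of freedom. Because the arrays of replicate 2 differed in scaling, number format and spike controls, the same fit was run within the batch of replicates 1 and 3, 2 against 2 arrays with 2 residual degrees of freedom. That fit was chosen after the data were seen, the opposition of replicate 2 to the other pairs among them. Its values lead the text because 0 probe sets passed over all 6 arrays, and replicate 2 then gave 1 difference per gene with no test. All differences are cadmium minus control by label.

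Of the 22746 probe sets that are not controls, 13513 were named with 1 gene by the annotation used here, 503 with several and 8730 with none. Names were updated through the gene identifier to the TAIR10.1 RefSeq table, without its coordinates. A probe set with several genes or none was tested but is not named. For each gene the probe set with the highest mean signal was used. Of 537 genes in 23 lists fixed before the data were examined, 54 in 16 lists were tested, and 5 lists with at least 4 tested members were tested as sets with camera (preset correlation 0.01), and beside it with an estimated correlation and with fry, which compares a list with no other genes. The lists of nitrate and ammonium, ethylene, aquaporins, DNA damage, endodermis and suberin, xylem, and phloem genes had 0 tested members and are not analysed here. Of the 537 listed genes 59 had a named probe set, so most were missing for want of a name and not for low signal. The tested members may not represent their lists. Of 21 families set by gene symbol or synonym, 10 were tested as sets in a separate adjustment.

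Genes named in the text follow a rule fixed before the data were examined. It takes the 12 genes with the widest difference in each direction among those past the threshold, with groups that do not overlap, a brighter group above the median signal of 191 and 1 gene in the annotation. It adds up to 3 members each way from each list (the member with the widest difference where fewer than 2 passed), up to 2 each way from each family, and the reference genes. Other genes fixed by the rule that had no named probe set are not analysed here. Because 0 genes passed over all 6 arrays, the rule was applied within the batch, a choice made after the data were seen. Where the mean of the dimmer group was under 62.1, the 30th percentile of all signals, the fold was computed with lower signals set to that value and is given as "at least".

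RNA quality was measured as the log2 ratio of the 3' to the 5' signal of control transcripts. With 3 against 3 arrays an exact permutation test cannot give a two-sided p under 0.1, and the actin ratio gave an exact p of 0.6 between the groups and GAPDH 0.7. The ubiquitin ratio gave 0.1, the smallest possible, and was higher on the cadmium array by 0.31, 0.38 and 0.30 in replicates 1, 2 and 3.

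The fits were tested on simulated data for 15909 probe sets, with 50 genes changed at each of 4 sizes. In the fit of 3 against 3 arrays, 0%, 0%, 0% and 22% were recovered at log2 changes of 1, 2, 3 and 4. That fit gave 2 false calls. The fit within the batch recovered 0%, 24%, 64% and 56% at the same changes, with 0 false calls. False calls on simulated data do not measure those on the real arrays, whose differences were shared across genes. The real differences of replicates 1 and 3 correlated with r = 0.77, and those of replicates 1 and 2 with r = -0.68. The spread over all arrays includes the scaling and the opposition of replicate 2. The low recovery of 3 against 3 arrays therefore cannot be put down to the number of arrays alone.

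The alternatives tried were a replicate block, quantile normalization, median centring, no filter or a filter at the median signal, an offset or a floor of 62.1 before log2, eBayes without a trend, array weights, each array left out, stricter thresholds and probe sets without a suffix for shared targets. Added after the data were seen were the batch as a block, each replicate pair left out, and the same alternatives within the batch. Figures were drawn with matplotlib 3.10.9.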

Results

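Transcripts were measured in roots of 4-week-old Arabidopsis thaliana plants of the Col-0 accession, kept in hydroponic culture and exposed for 6 h to 200 µM cadmium, a toxic heavy metal, or left without it. Each sample was hybridised to an Affymetrix ATH1 array, which carries 22810 probe sets, and signals are in the linear MAS5 units of the deposited values. There were 6 arrays, 3 labelled control and 3 labelled cadmium, with replicate numbers 1 to 3 in each group. The labels call the replicates biological. The number of arrays limits the precision of every value.

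The arrays of replicate 2 differed from the rest in scaling and in some RNA quality controls. The 2% trimmed mean of the signals was 500 on each array of replicates 1 and 3, whereas it was 216 on the control and 227 on the cadmium array of replicate 2. In 1 pair of actin control probe sets the 3' signal exceeded the 5' signal by 2.05 and 3.22 (log2) on the control and cadmium arrays of replicate 2. On the other 4 arrays it did so by 0.07 to 0.34. A second actin pair gave 3.46 and 3.73 on replicate 2 and 2.41 to 2.99 on the others. A second GAPDH pair gave 2.02 and 1.67 against -0.60 to -0.19. The ubiquitin ratio did not set replicate 2 apart (-0.02 and 0.37, against 0.08 to 0.59). The ubiquitin ratio was higher on each cadmium array than on each control array (group means 0.44 and 0.11). Replicates 1 and 3 are therefore treated as 1 processing batch of 2 arrays labelled control and 2 labelled cadmium, and replicate 2 as a pair without replication. Because the direction of many genes depended on the replicate, arrays are named throughout by the group their labels give.

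**Figure D1:**
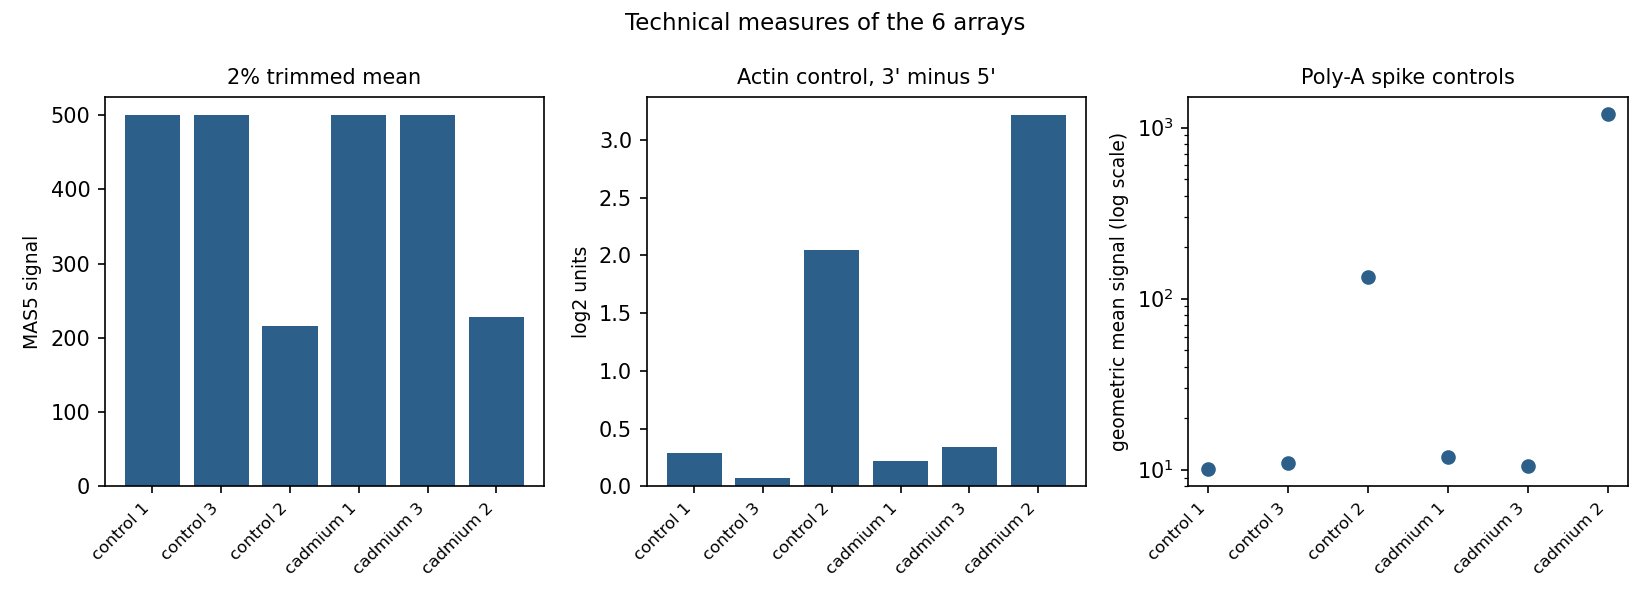
Technical measures of the 6 arrays: the 2% trimmed mean of the deposited signals (bars), the log2 ratio of the 3' to the 5' actin control signal (bars), and the geometric mean signal of 12 poly-A spike control probe sets (points, log axis). Both arrays of replicate 2 stand apart from the other 4, with trimmed means of 216 and 227 against 500.

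The comparison of the groups asks which root transcripts differ after 6 h of cadmium. Within replicates 1 and 3, 4 of 7 heat shock, 2 of 4 sulfate assimilation and 2 of 5 oxidative stress genes were lower past the threshold on the arrays labelled cadmium, and 2 of 2 glucosinolate genes were higher. In replicate 2, where nothing could be tested, the tested members of these lists with replicates 1 and 3 alike and replicate 2 opposed were 7 of 7, 3 of 4, 3 of 5 and 2 of 2. The same held for 4 of 4 reference genes, with median differences of 0.07, -0.21 and 0.19 in replicates 1, 2 and 3. Of all tested probe sets with replicates 1 and 3 alike, 9500 were opposed in replicate 2 and 2760 were not. AT1G53540, a small heat shock protein, had signals of 11799 and 2682 on the control arrays of replicates 1 and 3 and 81.4 and 48.8 on the cadmium arrays, but in replicate 2 its signal was 51.6 on the control and 5569 on the cadmium array. BCAT4, the aminotransferase that starts chain elongation of methionine for glucosinolates, had signals of 958 and 296 on the control arrays and 7402 and 7577 on the cadmium arrays of replicates 1 and 3, against 2510 on the control and 856 on the cadmium array of replicate 2. Over all 6 arrays 0 of 15909 probe sets passed the threshold in limma (lowest adjusted p = 1), and 84 had an unadjusted p under 0.05. Groups of all 6 arrays did not overlap for 172 probe sets (1.08%), where chance gives 10% for arrays scaled alike. The lower scaling of replicate 2 falls on 1 array of each group and makes such separation rarer, so these shares cannot be compared. Within the batch of replicates 1 and 3, 721 probe sets passed the threshold, 205 higher and 516 lower on the cadmium arrays, and 719 of them differed at least 2-fold. The excess of lower ones depended on the method, and counted without a model, the groups of the batch did not overlap for 6494 higher and 2686 lower probe sets. With a replicate block too, more of the probe sets past the threshold were higher than lower. The count without a model takes in small differences, and the median over all tested probe sets was 0.22 in the batch. After quantile normalization 125 higher and 501 lower passed, and after median centring 122 and 627.

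**Figure D2:**
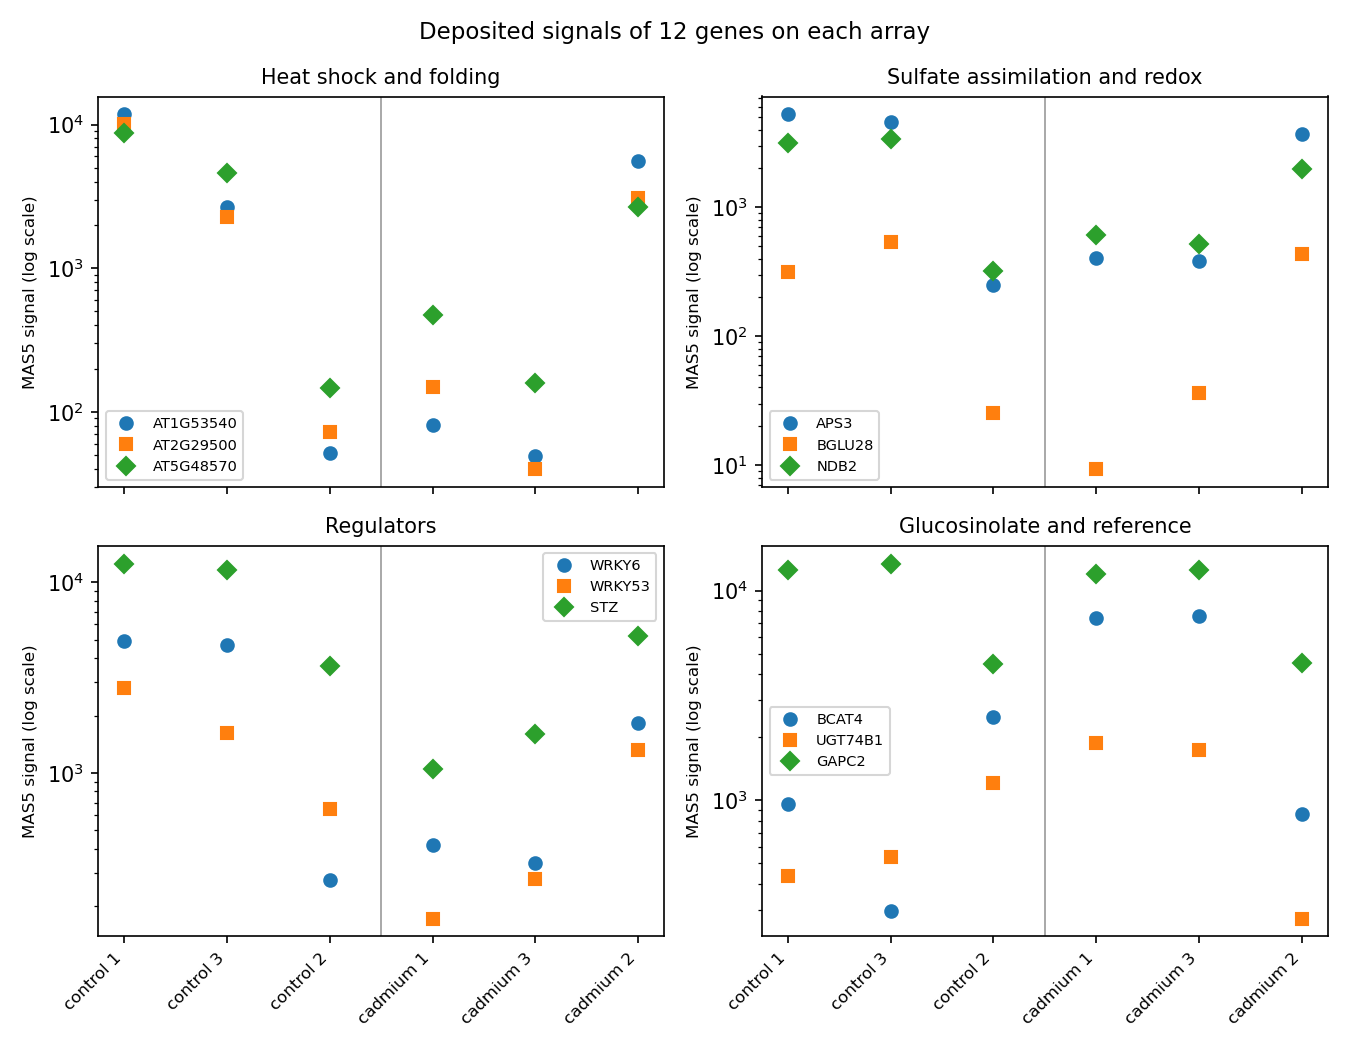
Deposited MAS5 signals (log axis) of 12 genes on the 3 arrays labelled control and the 3 labelled cadmium, 1 point per gene and array, with replicate 2 drawn last in each group. APS3 reads 5272 and 4617 on control arrays 1 and 3 but 251 on control array 2, and 403 and 386 on cadmium arrays 1 and 3 but 3730 on cadmium array 2, whereas the reference gene GAPC2 differs by at most 0.10 (log2) within any pair.

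Heat shock and protein folding genes showed the widest separation of the fixed lists. Within the batch, 4 of the 7 tested members were lower on the cadmium arrays and 0 higher, while 7 were lower when adjusted over the list alone. AT1G53540 was 89.2-fold lower (log2 difference -6.48 ± 0.72 SE, adjusted p = 0.0201) and AT2G29500, another small heat shock protein, 62.1-fold lower (adjusted p = 0.0360). Both had a signal under 62.1 on cadmium array 3. With signals floored at 62.1 they were 79.2-fold and 49.7-fold lower (adjusted p = 0.0253 and 0.0403). AT5G48570, a peptidyl-prolyl isomerase of the FKBP type, was 23.3-fold lower (adjusted p = 0.0275). The median difference of the list was -5.29 in replicate 1, -5.78 in replicate 3 and 5.41 in replicate 2, and 7 of 7 members were opposed in replicate 2. With signals under 62.1 set to that value, these medians were -5.29, -4.86 and 4.64. Camera placed the list below the other genes within the batch (adjusted p = 3.59e-10) and over all 6 arrays (adjusted p = 7.49e-11). Neither call was kept when the correlation between members was estimated (adjusted p = 0.197 within the batch and 0.244 over all 6 arrays). The estimates were 0.91 and 0.96. Camera with an estimated correlation also uses only the residual degrees of freedom, 2 within the batch and 4 over all 6 arrays. The loss therefore cannot be put down to correlation alone. The call over all 6 arrays also ended without the pair of replicate 1 (adjusted p = 0.147) or that of replicate 3 (adjusted p = 0.472). Fry asks another question, whether the members move 1 way on balance, without comparing them with other genes, and it gave adjusted p = 0.0686 and 0.816.

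Of the 4 tested genes of sulfate uptake and assimilation, 2 were lower on the cadmium arrays of the batch and 2 did not pass the threshold, with the same 2 when adjusted over the list alone. APS3, an ATP sulfurylase that activates sulfate, was 12.5-fold lower (log2 difference -3.65 ± 0.20 SE, adjusted p = 0.00915) and 3.89 higher on the log2 scale in replicate 2. BGLU28, a beta-glucosidase, was at least 6.62-fold lower (adjusted p = 0.0431) and at least 2.81 higher on the log2 scale in replicate 2. Camera placed this list low within the batch (adjusted p = 0.000835) and over all 6 arrays (adjusted p = 0.0104), which was lost with an estimated correlation (adjusted p = 0.178 and 0.244). The estimates were -0.24 and 0.28, so within the batch correlation between members does not account for the loss. Fry gave adjusted p = 0.0195 and 0.816. In the list of oxidative stress and antioxidants, 2 of 5 members were lower, also when adjusted over the list alone. STZ, a zinc finger repressor also known as ZAT10, was 9.32-fold lower (log2 difference -3.22 ± 0.25 SE, adjusted p = 0.0121) with a replicate 2 difference of 0.52, and NDB2, an external NADH dehydrogenase of mitochondria, was 5.78-fold lower (adjusted p = 0.0128) with a replicate 2 difference of 2.63. Camera called this list low within the batch (adjusted p = 0.000835) and over all 6 arrays (adjusted p = 0.0344), again not with an estimated correlation (adjusted p = 0.178 and 0.360). Here the estimates were -0.18 and 0.59, so the loss within the batch again does not come from correlation between members. For movement in 1 direction fry gave adjusted p = 0.0162 and 0.816.

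Of 3 listed WRKY transcription factors, 2 were lower on the cadmium arrays of the batch, and 3 when adjusted over the list alone. WRKY6 was 12.7-fold lower (log2 difference -3.67 ± 0.21 SE, adjusted p = 0.00934) and WRKY53 9.67-fold lower (adjusted p = 0.0211), with replicate 2 differences of 2.75 and 1.03. The wider family of 6 WRKY genes was low by camera within the batch (adjusted p = 0.000343, with an estimated correlation adjusted p = 0.372) and over all 6 arrays (adjusted p = 6.94e-05, with an estimated correlation adjusted p = 0.212). Its fry values were 0.0256 and 0.914 after adjustment. The correlation between members of the WRKY family was estimated at -0.098 within the batch and 0.46 over all 6 arrays. Among 8 calmodulin or calcium-binding genes, CML37 was at least 23.4-fold lower (adjusted p = 0.0495) and CML42 6.75-fold lower (adjusted p = 0.0189). With signals floored at 62.1, CML37 no longer passed (adjusted p = 0.0769). That family was low by camera within the batch (adjusted p = 0.00417) and over all 6 arrays (adjusted p = 0.000275), and neither held with an estimated correlation (adjusted p = 0.372 and 0.212). Its fry values were 0.189 and 0.914. The correlation was estimated at -0.00085 within the batch and 0.17 over all 6 arrays. Correlation between members therefore does not account for the loss within the batch in the WRKY or the calmodulin family. Class III peroxidases, secreted enzymes of the cell wall, were low by camera over all 6 arrays (adjusted p = 0.000275, with an estimated correlation adjusted p = 0.199) with 0 of 6 members past the threshold in either fit, and within the batch the family gave adjusted p = 0.118.

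Genes of glucosinolate and camalexin synthesis were higher on the cadmium arrays of the batch in 2 of 2 tested members, also when adjusted over the list alone. BCAT4 was 14.1-fold higher (log2 difference 3.82 ± 0.55 SE, adjusted p = 0.0332) and UGT74B1, the glucosyltransferase of the glucosinolate core, 3.72-fold higher (adjusted p = 0.0211), with replicate 2 differences of -1.55 and -2.16. In the glutathione S-transferases, 1 of 8 members was higher, and 3 higher and 2 lower when adjusted over the list alone. GSTU20 was 8.51-fold higher (log2 difference 3.09 ± 0.43 SE, adjusted p = 0.0313), and its replicate 2 difference was 0.62, in the direction of the other pairs. Camera called the list high over all 6 arrays (adjusted p = 0.0214, with an estimated correlation adjusted p = 0.360) and gave the direction low within the batch (adjusted p = 0.714), although the list's median difference there was 0.32.

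The remaining lists had few tested members. In the phenylpropanoid list 1 of 3 was lower, CCR2, a cinnamoyl-CoA reductase (12.1-fold, adjusted p = 0.0235), and adjusted over the list alone 1 was lower and 1 higher. In the iron uptake list 1 of 3 was lower, with 1 adjusted over the list alone: AT3G13610, a hydroxylase of coumarin synthesis (2.23-fold, adjusted p = 0.0313), beside AT1G47400, a peptide of iron signalling, at -1.89 ± 1.21 SE (adjusted p = 0.384). With the floor AT1G47400 was at -0.78 (adjusted p = 0.520). The only tested jasmonate gene, OPCL1, a CoA ligase of jasmonate synthesis, was 2.90-fold lower (adjusted p = 0.0326), and 1 of 1 passed adjusted over the list alone. The only tested gene of the abscisic acid list, the dehydrin COR47, had a difference of -1.04 (adjusted p = 0.0558 over all genes, and 1 of 1 passed adjusted over the list alone). In the root hair list 0 of 3 passed, and 2 adjusted over the list alone. XTH26, a wall enzyme of root hairs, had signals of 3.63 and 16.1 on the control and 130 and 362 on the cadmium arrays of the batch, at least 3.50-fold higher (adjusted p = 0.0778, and 0.132 with the floor). In replicate 2 the signals were 42.8 and 83.5, so the control array was under 62.1 and the cadmium array above it in 3 of 3 pairs. Over all 6 arrays XTH26 passed adjusted over the list alone (adjusted p = 0.00633, and 0.0436 with the floor), though not over all genes (adjusted p = 1). In the cell cycle list 0 of 3 passed and 3 were higher adjusted over the list alone, with AUR1, an Aurora kinase, at 1.05 (adjusted p = 0.110). Glutathione and phytochelatin genes (0 of 2, GR1 at -1.11, adjusted p = 0.240), other metal handling genes (0 of 2, ZIP9 at -0.61, adjusted p = 0.472) and shoot photosynthesis genes (0 of 3, PRK at 0.41, adjusted p = 0.421) had no member past the threshold, and 0 adjusted over the list alone.

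Among 4 reference genes 0 passed, over all genes or adjusted over the list alone. Their differences within the batch were -0.08 for GAPC2, 0.08 for PEX4, 0.19 for AT4G34270 and 0.68 for AT2G28390, beside a median of 0.22 over all tested probe sets, and the first turned positive after quantile normalization and the second negative after median centring. In the keyword families, UGT73B5 was 8.58-fold and UGT73B4 at least 5.32-fold lower, both glucosyltransferases (adjusted p = 0.0170 and 0.0262), among 3 lower and 1 higher of 29. CYP71B6 was the only 1 of 11 cytochrome P450 genes past the threshold (4.44-fold lower, adjusted p = 0.0139). EXGT-A3, a xyloglucan endotransglucosylase, was 2.97-fold lower (adjusted p = 0.0320), EXLA2, an expansin-like gene, at least 4.00-fold lower (adjusted p = 0.0486, and 0.0905 with the floor), and HTB2, a histone H2B, 3.93-fold higher (adjusted p = 0.0358).

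The genes with the widest differences in the batch, 12 in each direction, included several without a list. AT5G52760 was at least 12.5-fold lower and AT4G37290 at least 23.9-fold lower (adjusted p = 0.0121 and 0.00915), followed by AT2G23270, AT4G23030 and AT5G22530, each at least 9.39-fold lower. AT1G54050, a small heat shock protein, was 46.1-fold lower (adjusted p = 0.0128) and AT1G66080 26.0-fold lower (adjusted p = 0.0173). Among the higher genes, AT3G57010 was at least 7.68-fold higher (adjusted p = 0.0142), AT5G48110 8.62-fold (adjusted p = 0.0211), AT5G04960 7.26-fold (adjusted p = 0.0211) and AT1G21440 7.11-fold (adjusted p = 0.0165). AT3G45700, AT4G02090, AT5G02360, AT5G67150, AT5G47790 and AT2G37700 were at least 3.29-fold higher, though AT5G47790 and AT5G02360 did not pass with the floor (adjusted p = 0.0645 and 0.0648). In replicate 2, 23 of these 24 genes differed in the opposite direction, the exception being GSTU20.

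The opposition extended beyond the named genes. Across the 15909 probe sets, the differences of replicates 1 and 3 correlated with r = 0.77, whereas those of replicate 2 correlated with r = -0.68 with replicate 1 and r = -0.63 with replicate 3. These correlations are across genes, which are not independent replicates. Of all 15909 probe sets, 9500 (59.7%) had replicates 1 and 3 alike and replicate 2 opposed, and 2760 (17.3%) went the same way in 3 of 3 pairs. Of the 721 probe sets past the threshold in the batch, 679 (94.2%) were opposed in replicate 2, namely 193 of the 205 higher and 486 of the 516 lower. Of 974 probe sets with at least a 2-fold difference in every pair, 964 had replicates 1 and 3 alike and replicate 2 opposed, and 9 went the same way in 3 of 3 pairs.

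**Figure D3:**
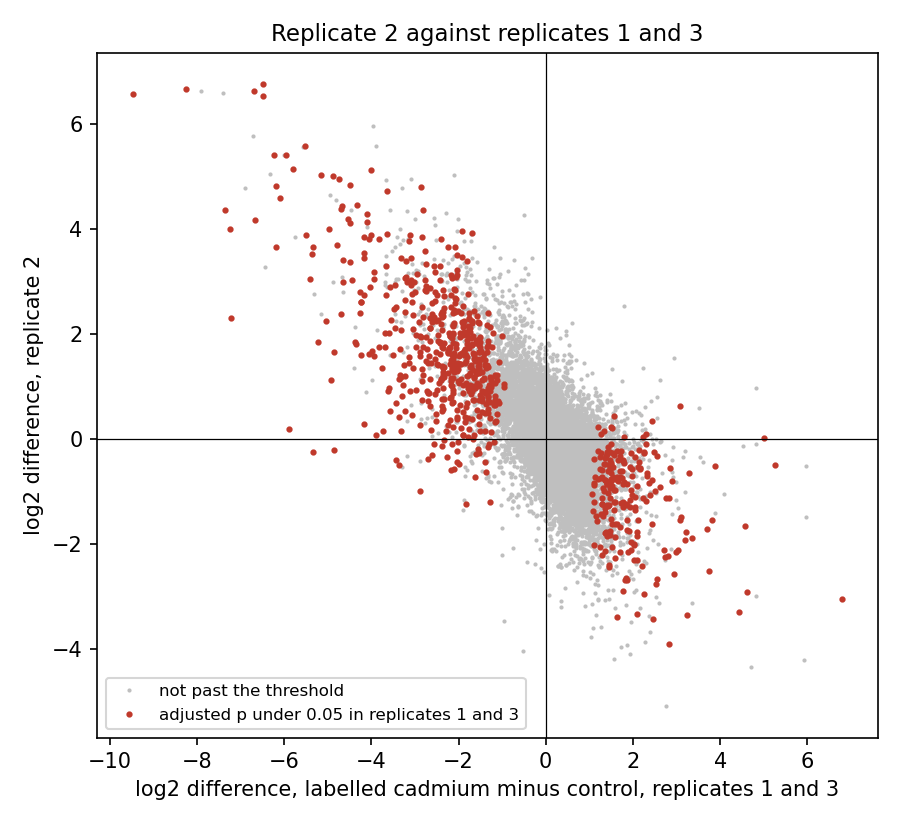
Log2 difference between the arrays labelled cadmium and control in replicate 2 (vertical) against that in replicates 1 and 3 (horizontal), 1 point per probe set for 15909 probe sets, with the 721 past the threshold in replicates 1 and 3 in red. Most red points lie in the upper left and lower right quadrants, where 679 of the 721 fall.

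Both counts depended on the arrays and their weights. With array weights, which were 0.20 and 0.12 for the control and cadmium arrays of replicate 2 and 1.32 to 3.56 for the others, 1560 probe sets passed over all 6 arrays, while the batch count was 142 without cadmium replicate 1, 146 without cadmium replicate 3 and 1266 without control replicate 3, and 17, 15 and 37 of the 40 named genes past the threshold were still past it. After median centring of the arrays, 122 higher and 627 lower probe sets passed in the batch.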

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

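The tests in this part, except the counts of probe sets and lists past the threshold over other splits of the arrays, were chosen after the results they address were seen.

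The heat shock list was flagged because its members moved 1 way in replicates 1 and 3 and the other way in replicate 2, where the median difference was 5.41 on the log2 scale (-5.29 and -5.78 in the other pairs); that difference between replicates was not tested. Of the probe sets with replicates 1 and 3 alike, 9500 were opposed in replicate 2 and 2760 were not. Of those past the threshold in the batch, 94.2% were opposed. The opposition is therefore not particular to this list. A different scaling factor for the replicate 2 arrays shifts all log2 differences of that pair alike, so it cannot change their correlation with the other pairs. A different distribution of their signals is argued against, since that correlation was -0.69 after quantile normalization. So is RNA quality differing within pairs 1 and 3, where the 3' to 5' ratio of no control transcript changed by more than 0.38. Within pair 2 the actin ratio changed by 1.17, beside 0.20 for GAPDH and 0.38 for ubiquitin. The second probe set pairs of these transcripts changed by 0.26 for actin, -0.36 for GAPDH and 0.21 for ubiquitin. The large change thus rests on 1 actin pair, and a part from RNA quality there stays open. Labels exchanged within some of the pairs may account for it: higher and lower genes were opposed alike, the control array of replicate 2 ranked genes more like the cadmium arrays of the batch (Spearman 0.83 and 0.85) than the control arrays (0.78 and 0.80), and its cadmium array more like the control arrays (0.83 and 0.81 against 0.67 and 0.69). An opposite response of the replicate 2 plants to cadmium would look alike and was not tested.

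Which pairs would carry exchanged labels stays open. The hypothesis that the labels of replicates 1 and 3 were exchanged predicts that heat shock genes, which as background are known to rise under cadmium and other protein-damaging stress, are higher on the control arrays of those pairs and lower on that of replicate 2, and this held for 7 of 7 tested members. That count restates the pattern that drew attention to the list, so it decides nothing about the labels. The hypothesis cannot be told apart from a stress of the plants labelled control in replicates 1 and 3, because no marker of cadmium independent of the labels was analysed here. No array was regrouped.

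Probe sets of the mitochondrial genome were flagged because their median difference in replicate 2 was 2.98, with 22 of 23 higher on the cadmium array, against -2.38 and -0.90 in replicates 1 and 3, with 23 of 23 higher on the control array in each; that difference between replicates was not tested. Less selective priming on poly-A RNA would raise plastid probe sets too. It is argued against in replicate 1, where the plastid median was 0.20 and 18 of 69 were higher on the control array. In replicate 2, 51 of 69 were higher on the cadmium array, the direction of the mitochondrial ones. Their median of 0.46 was 0.153 of the mitochondrial one, so a smaller part from priming stays open there. The 25S ribosomal RNA probe set read 2746 on the control and 1928 on the cadmium array of replicate 2, and 66.1 to 303 on the other 4. Its signal was higher on the control array in replicates 1 and 2 and on the cadmium array in replicate 3. Priming that differs between replicate 2 and the other arrays was not tested. The hypothesis that mitochondrial probe sets follow the same contrast as the heat shock genes stays open, with the replicate 3 median at 0.378 of that in replicate 1, in the same direction but smaller. No biological explanation was tested.

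Poly-A spike controls, bacterial transcripts outside the comparisons, were flagged for a geometric mean signal of 1196 on the cadmium array of replicate 2, beside 133 on its control array and 10.2 to 11.9 on the other 4 arrays.

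The design has 10 splits of the 6 arrays into groups of 3, too few for a share under 0.05. For single genes, 10 of 10 splits gave as many probe sets as the real split's 0, and the highest of the others was 128. That split set control arrays 1 and 3 and cadmium array 2 against the rest, which is the exchange of the replicate 2 labels, so its count restates the opposition above. The 4 splits that keep the arrays of replicate 2 together, as the processing batch does, gave 1378 to 4755 probe sets with an unadjusted p under 0.05. The split with exchanged replicate 2 labels gave 1098 and the real one 84. Signals were used as deposited, so in those 4 splits the lower scaling of replicate 2 falls on 1 side and can raise the count by itself. In the other splits it falls on both sides, so these counts cannot be compared as measures of a structure of the samples. For gene lists, 1 of 10 splits, the real one, gave as many as its 4, and the highest of the others was 3. Within the batch 3 lists were called.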

How the results depend on the processing

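Alternatives that use the batch of replicates 1 and 3, the batch as a block or pairs left out were chosen after the data were seen. Over all 6 arrays the count of 0 probe sets stayed at 0 except as follows. With array weights it was 1560, of which 702 also passed within the batch in the same direction. Those weights stopped short of the convergence tolerance. Groups did not overlap for 172 (1.08%, where chance gives 10% only for arrays scaled alike). Without both arrays of replicate 2 the count was 721. When single arrays were left out it was 0 to 1, the 1 without control replicate 1. The replicate block gave 0 probe sets and 1 list in place of 4. Shared numbers did not pair the arrays by the rule used, since deviations of same-numbered arrays from their group means correlated by 0.11, -0.04 and 0.29. The cadmium array of replicate 2 correlated best with control 1, not with its own number. Those group means include replicate 2, whose opposition pushes same-numbered deviations apart, so these values cannot decide whether the numbers pair the arrays. Within the batch of 2 pairs, where replicate 2 is left out, the correlation was 0.53. The 4 lists became 1, heat shock, with quantile normalization, median centring or the batch as a block (also with quantile normalization). Without the pair of replicate 1 or of replicate 3 they became 1 as well, but that was the glutathione S-transferases (adjusted p = 0.000734 and 6.94e-05). They became 0 with an estimated correlation, and 2 to 3 with single arrays left out; fry, which compares a list with no other genes, called 0.

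Within the batch, 721 probe sets became 3521 with the replicate block (721 of the 721 among them, with 2012 higher and 1509 lower in place of 205 and 516, so the majority turned), 353 without the trend, 13 at an adjusted p under 0.01, 9180 (57.7%, 6494 higher and 2686 lower) for groups that do not overlap, where chance gives 33.3%, and 142 to 1266 with single arrays left out, when the lone array of a group is assumed to vary like the others. With the replicate block, GR1 (adjusted p = 0.00595), COR47 (0.00332), XTH26 (0.0115), AUR1 (0.0292) and AT1G47400 (0.0489) also passed. The 3 lists stayed 3 with single arrays left out, became 0 with an estimated correlation, and fry called 2. The correlation of replicate 2 with the other pairs, -0.70, was -0.55 without the filter and -0.83 over the probe sets past the threshold. The causes of these shifts were not tested, beyond the fewer arrays or stricter rules themselves.

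Of the 40 named genes past the threshold, the 394 values under the 10 other alternatives kept their direction, and 365 stayed past it. Among named genes that did not pass, the sign turned for GAPC2 (0.10, quantile normalization), PEX4 (-0.11, median centring), and, without control replicate 3, ZIP9 (-1.29 to 0.066 over the arrays left out) and AT4G34270 (-0.022 to 0.40). Signals under 62.1 set a limit for the dimmer group of many genes.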

Other observations

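The genes in this part were picked out after their values were seen. AT5G49280 was the only named gene among the 9 probe sets that differed at least 2-fold the same way in 3 of 3 pairs. Its signal was lower on the cadmium array by a log2 difference of -1.08, -1.21 and -1.49 in replicates 1, 2 and 3 (-1.26 ± 0.84 SE over all 6 arrays, limma adjusted p = 1). That fit had no block, so its SE includes the scaling difference between replicate 2 and the rest. The reference gene GAPC2, which differed by at most 0.10 within any pair, had an SE of 0.72 there.

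The mitochondrial-genome probe sets stood for 16 genes. Control array 1 exceeded control array 3 by a median of 2.38 on the log2 scale in these probe sets, and cadmium array 1 exceeded cadmium array 3 by 1.11.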
